A study of Homo sapiens with 14 samples.

How the data were processed

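The deposited values were 2 tables that together cover the 14 RNA-seq libraries, each with 1 column per library and genes named by symbol. The first table held raw read counts per gene, unnormalised whole numbers as deposited by the authors, for 24729 genes. The second table held RPKM values, reads scaled by the authors to transcript length and library depth for each library, for 25268 genes, of which 539 were in that table alone. Per the labels, the authors' processing used TopHat, Cufflinks and DESeq with the human build hg19, without stated versions, annotation or counting tool. Per the labels, poly(A) RNA libraries were made with an unstranded kit, so the counts of genes that overlap on opposite strands, such as XIST and TSIX, cannot be told apart. Near-identical gene pairs such as HBG1 and HBG2, HBA1 and HBA2, or HSPA1A and HSPA1B share reads whose assignment is uncertain.

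Groups were taken from the labels and held 2 WT libraries and 3 libraries each of sgGal4, sgHS2, sgHBG and sgHS1-5. Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr (minimum count 10, minimum total count 15), which left 14406 genes. TMM factors scaled the libraries, all 14 libraries entered a fit with a mean per group (9 residual degrees of freedom, common dispersion 0.0323), and groups were compared with the quasi-likelihood F test. Adjusted p values are Benjamini-Hochberg values over the genes tested in a comparison, and a gene was called at an adjusted p under 0.05. Unless another test is named, adjusted p refers to this edgeR test. The log2 differences are fitted values with their standard error (SE), and levels are CPM (counts relative to library size) scaled by TMM, given as mean and standard deviation (SD). The planned comparisons were each targeting sgRNA against sgGal4, sgGal4 against WT, and the 3 pairs of targeting sgRNAs. Comparisons of targeting sgRNAs with WT were added later.

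There were 24 gene lists: β-globin cluster, genes neighbouring the β-globin cluster, α-globin cluster, regulators of globin transcription, erythroid membrane, heme biosynthesis, megakaryocyte, myeloid, lymphoid, fibroblast and epithelial, cholesterol synthesis, glycolysis and hypoxia, unfolded protein response, heat shock, interferon response, MHC and antigen processing, biotin enzymes, cell adhesion, p53 and DNA damage, immediate early, BCR-ABL and STAT5 targets, proliferation, ribosomal proteins, and replication-dependent histones. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run as alternatives. The fry p asks whether the genes of a list move on balance in a single direction, and it does not compare them with other genes.

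Genes are named by a fixed rule. Among genes with an adjusted p under 0.05, a mean of at least 1 CPM over both groups and no overlap between the groups, the 10 with the highest and the 10 with the lowest log2 difference were named, or 3 in each direction between targeting sgRNAs. For groups of 3 and 3 libraries, a lack of overlap arises by chance in 10% of genes. Every gene of the β-globin cluster and up to 4 members of each other list with the lowest p were named as well. The groups, tests, gene lists, naming rule and other settings named first in the next paragraph were fixed before the data were examined. A fold against a group with 0 counts is a lower bound computed with 3 counts over the group, and a fold against 1 to 3 counts is given with its exact binomial 95% interval. These intervals and bounds cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

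The other settings fixed in advance were RLE size factors, library sizes without globin genes, no low-count filter, a filter of 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma voom, fits with only the compared groups, a block for the replicate number, a minimum of 2-fold change, and leaving out each library in turn. RPKM values were tested with limma-trend after adding 1 or 0.1, with and without a filter on low values. The log2 differences of RPKM values include the added amount, so for genes at low levels they are smaller than log2 fold changes. After the data were seen, fits were added without sgGal4 1 and sgHS2 2, without sgHS1-5 2 and 3 (the remaining sgHS1-5 library was then assumed to vary like the other groups), and without these 4 libraries. The replicate numbers did not pair libraries across groups, so the block was used only as an alternative.

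The procedure was tested on simulated data with 200 changed genes per comparison. Of genes changed by 2-fold, it recovered 74% for sgHS2, 78% for sgHBG and 66% for sgHS1-5 against sgGal4 and 64% for sgGal4 against WT. False calls were 1.18%, 2.84%, 2.42% and 7.56% of calls, in the same order. The simulated counts were drawn independently for each gene, and the changed genes came from those above a minimum level. No simulated library departed from its group as a whole, as some real libraries did, and far fewer genes changed than were called in the real data. The rates describe the simulated setting only. Chromosomes were matched by symbol in RefSeq annotation of GRCh38.p14 for 14145 genes (98.2%) and transcript lengths in GENCODE 29 for 13999 genes (97.2%). Since the files used another build, only chromosome names, gene order and lengths were used. Figures were drawn with matplotlib 3.10.9. The 539 genes of the RPKM table alone have no counts and were not used in the count tests. Results for some single genes are not reported here.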

Results

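RNA-seq was performed on 14 libraries of K562 cells, a human chronic myeloid leukemia line with erythroid and megakaryocytic features. In 4 groups the cells stably expressed a catalytically inactive Cas9 (dCas9) with a Flag and biotin-acceptor tag, the biotin ligase BirA and sgRNAs. The sgRNAs targeted HS2, an enhancer of the β-globin locus control region (sgHS2, n = 3), the promoters of the fetal globin genes (sgHBG, n = 3), several elements of the locus control region (sgHS1-5, n = 3) or no human sequence (sgGal4, n = 3). The fifth group was unmodified cells (WT, n = 2). The libraries held 5694448 to 11335831 counted reads. Libraries WT 1 and 2 had 10176582 and 10733710 reads, sgGal4 1 to 3 had 9498578, 10782074 and 11335831 reads, and sgHS2 1 to 3 had 11285274, 9765587 and 10622959 reads. The sgHBG libraries had 9781552, 10870414 and 11116665 reads and the sgHS1-5 libraries 5694448, 6773888 and 6722849 reads. A count of 0 allowed a level of up to 0.265 CPM in the deepest library (sgGal4 3) and 0.527 CPM in the shallowest (sgHS1-5 1). The labels do not say whether replicates were separate cultures, so p values measure the spread between these libraries only, which may be technical. Each sgRNA group is its own cell population, so an effect of its sgRNAs cannot be told apart from other differences between populations. A difference from sgGal4 may also lie in the sgGal4 cells, which themselves differed from WT. With the preset correlation, the cholesterol synthesis, ribosomal protein and erythroid membrane lists moved in sgGal4 against WT and the opposite way in each targeting group against sgGal4. Other lists, such as the megakaryocyte list, did not.

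Replicates differed little in the WT and sgHBG groups and more in the others. The χ² per degree of freedom between replicates, which is near 1 when counting error alone separates them, was 1.67 for WT and 1.25 to 1.44 for sgHBG. It was 1.49 between sgGal4 2 and 3 but 90.1 and 93.9 between these and sgGal4 1. In sgHS2 it was 1.76 between replicates 1 and 3 and 17.3 and 16.6 against replicate 2. In sgHS1-5 it was 3.10 between replicates 1 and 3, 18.4 between 1 and 2 and 11.9 between 2 and 3. Library sgGal4 1 had low levels of long transcripts and high levels of short ones, with median log2 deviations from its group of −0.42 for the longest 20% of transcripts and 0.44 for the shortest 20%. EEF1A1, a translation elongation factor, took 4.85% of its reads. The sgHS1-5 libraries, 2 and 3 above all, held transcripts nearly absent from the other groups. A set of 138 transcripts was chosen for no more than 0.1 CPM on average elsewhere and at least 5 CPM in any sgHS1-5 library. They summed to 2090 and 508 CPM in sgHS1-5 2 and 3, against 77.2 CPM in sgHS1-5 1 and 3.32 to 6.28 CPM elsewhere. The choice itself sets the gap to the other groups.

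**Figure D1:**
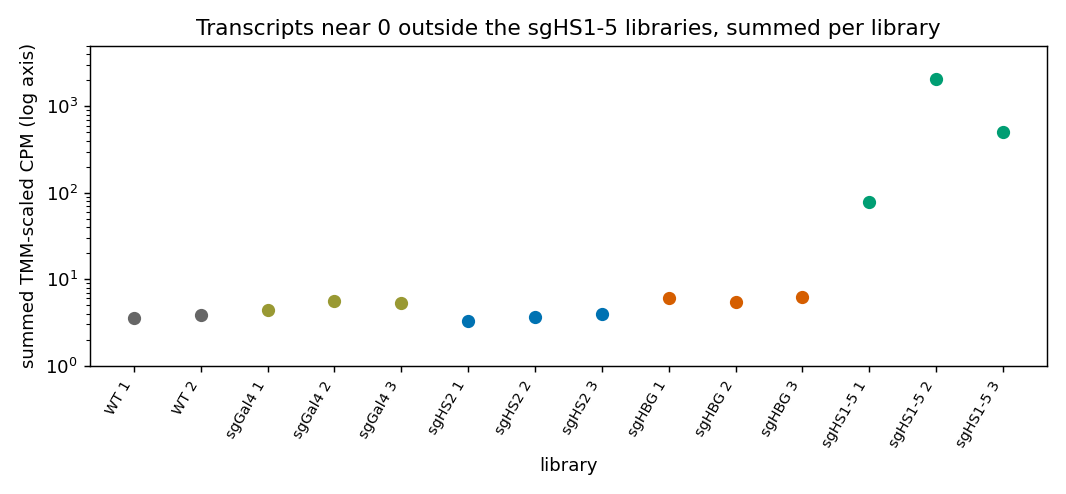
Summed level (CPM, log axis) of 138 transcripts, with a point per library for the 5 groups. The transcripts were chosen for levels near 0 outside sgHS1-5 and at least 5 CPM in any sgHS1-5 library. The 3 sgHS1-5 libraries lie at 77.2, 2090 and 508 CPM and the other 11 between 3.32 and 6.28 CPM.

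The comparison of sgHS2 with sgGal4 addresses which genes differ when dCas9 is directed to the HS2 enhancer. HBE1, the embryonic β-like globin gene, was 2.03-fold higher in sgHS2 (693 ± 116 CPM, SD, n = 3) than in sgGal4 (341 ± 176 CPM, n = 3), a log2 difference of 1.02 ± 0.28 (SE, adjusted p = 0.0143). HBG2, a fetal globin gene, was 2.87-fold higher (271 ± 45.9 against 94.9 ± 61.7 CPM, log2 1.52 ± 0.33, adjusted p = 0.00433). HBG1, its near-identical neighbour, was 1.91-fold higher (142 ± 30.2 against 74.6 ± 48.1 CPM, log2 0.93 ± 0.33, adjusted p = 0.0476). The globin pseudogene HBBP1 was 2.67-fold higher (log2 1.42 ± 0.28, adjusted p = 0.00216). HBD, a minor adult globin gene, had a log2 difference of 0.53 ± 0.22 that was not called (adjusted p = 0.0832), and HBB, the main adult gene, had 1 read in sgHS2 and 0 in sgGal4. In the β-globin cluster, 4 of 5 tested genes rose and 0 fell, and 5 rose adjusted over the list alone (camera adjusted p = 0.0227; adjusted p = 0.58 with an estimated correlation). The call of HBE1 was lost without sgGal4 2 (log2 0.82, adjusted p = 0.0514) or sgHS2 2 (log2 0.88, adjusted p = 0.0513), and that of HBG1 without any library of either group except sgGal4 1 (log2 0.68 to 1.03), while the call of the list was lost without sgGal4 2, sgGal4 3 or sgHS2 2 (adjusted p = 0.0593, 0.0735 and 0.0725) and without sgHS1-5 2 and 3 (adjusted p = 0.0519). With only these 2 groups in the fit, HBE1 and HBG1 were not called (adjusted p = 0.0827 and 0.169), nor was HBG1 without sgHS1-5 2 and 3 (0.0594), while HBD was called with limma voom (0.0384). Without sgGal4 1 and sgHS2 2, the log2 differences were 1.36 for HBE1, 1.39 for HBG1, 2.02 for HBG2 and 0.73 for HBD, all called, and without sgGal4 1 alone those of HBG1 and HBG2 were 1.60 and 2.19.

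**Figure D2:**
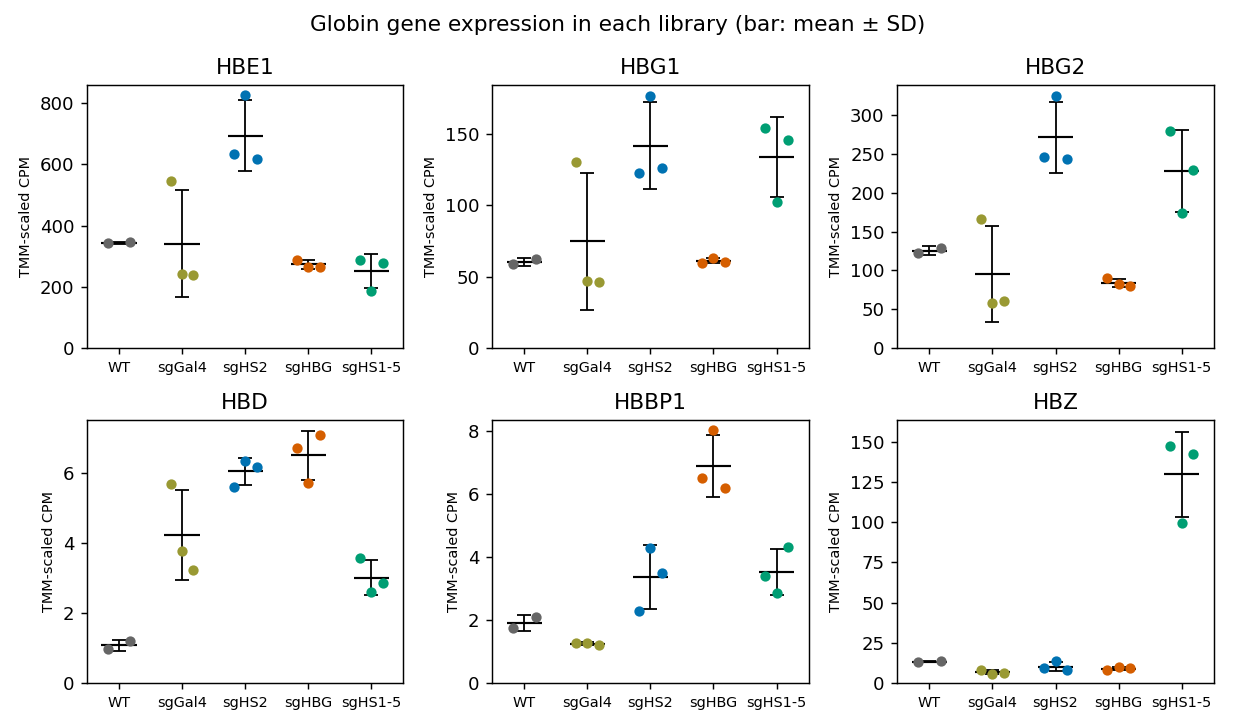
Levels (TMM-scaled CPM) of HBE1, HBG1, HBG2, HBD, HBBP1 and HBZ in WT, sgGal4, sgHS2, sgHBG and sgHS1-5, with a point per library and bars for the mean and SD. HBE1 averaged 693 CPM in sgHS2 and 251 to 344 CPM in the other groups, and HBZ averaged 129.8 CPM in sgHS1-5 and 6.63 to 13.2 CPM elsewhere.

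Outside the globin cluster, single genes differed widely between sgHS2 and sgGal4. Of the genes below, MAGEA8 and FN1 were also lower, and SLC6A15 higher, in sgGal4 than in WT. The mean level of FN1 was lower in sgHS2 than in WT. These differences thus cannot be assigned to sgHS2 rather than to sgGal4. MAGEA8, a cancer-testis antigen, was at least 43.5-fold higher in sgHS2 (4.58 ± 0.884 CPM, n = 3, against 0 counts, adjusted p = 6.03e-06). LIMCH1, an actomyosin regulator, was at least 23.9-fold higher (adjusted p = 6e-05). The matrix gene FN1 was 48.4-fold higher (66.7 ± 13.4 against 1.32 ± 0.417 CPM, log2 5.596 ± 0.69, adjusted p = 7.88e-05). CFI, a complement regulator, was 66.0-fold higher (log2 6.04 ± 0.47, adjusted p = 2.19e-06; 5.39 without sgGal4 3). XIST, the RNA of X inactivation, was 129-fold higher (log2 7.01 ± 0.33, adjusted p = 8.01e-08). Its antisense partner TSIX had a log2 difference of 6.25 in the counts but 0.01 in the RPKM values without a filter. Among the genes lowest in sgHS2, the chloride channel regulator CLCA1 was at least 51.4-fold lower (adjusted p = 0.000102). The collagen gene COL11A1 was 65.5-fold lower (0.161 ± 0.0625 against 11.2 ± 2.1 CPM, log2 −6.03 ± 0.37, adjusted p = 5.89e-07). The amino acid transporter SLC6A15 was 41.4-fold lower (1.197 ± 0.163 against 50.1 ± 9.32 CPM, log2 −5.37 ± 0.22, adjusted p = 7.56e-08).

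The cholesterol synthesis and proliferation lists fell in sgHS2, and the glycolysis and hypoxia and the interferon response lists rose. In the cholesterol synthesis list 0 of 22 genes rose, 18 fell and 4 were not called, also adjusted over the list alone. An example was CYP51A1, a sterol demethylase (log2 −1.28 ± 0.09, 168 ± 7.48 against 409 ± 11 CPM). In the glycolysis and hypoxia list 18 of 29 genes rose and 0 fell, and 20 rose adjusted over the list alone. VEGFA, an angiogenic growth factor, was 2.98-fold higher and LDHA, lactate dehydrogenase, 2.32-fold higher. In the interferon response list 21 of 29 genes rose and 2 fell, or 21 and 3 adjusted over the list alone, with the RNA sensor IFIH1 6.97-fold higher (log2 2.80 ± 0.16, adjusted p = 1.78e-07). In the proliferation list 0 of 30 genes rose and 18 fell, or 21 adjusted over the list alone, and the replication licensing gene CDC6 was 2.17-fold lower. These 4 lists were called with the preset correlation (camera adjusted p = 6.78e-15, 2.06e-11, 3.58e-10 and 6.14e-07) and with an estimated correlation (adjusted p = 0.000203, 0.00849, 0.0131 and 0.0234).

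The erythroid membrane and lymphoid lists were called in sgHS2 with the preset correlation but not with an estimated correlation, and the heme biosynthesis list was not called. In the erythroid membrane list 12 of 29 genes rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.000585; adjusted p = 0.285 with an estimated correlation). DMTN, a membrane skeleton gene, was 3.40-fold higher. In the heme biosynthesis list 6 of 20 genes rose and 1 fell (camera adjusted p = 0.0534), and the list was called without sgGal4 1 (0.00503), sgHS2 1 (0.0435), sgHS2 3 (0.0432) or a low-count filter (0.0217). ALAS2, the erythroid enzyme of the first step, was 3.30-fold higher (log2 1.72 ± 0.18, adjusted p = 1.86e-05). In the lymphoid list 6 of 16 genes rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.021, 0.0551 without sgGal4 2; adjusted p = 0.634 with an estimated correlation), with CD3D, a T cell receptor component, at 15.4 ± 1.19 against 2.12 ± 1.52 CPM. In the MHC and antigen processing list 6 of 18 genes rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.0461; adjusted p = 0.666 with an estimated correlation). The MHC call was lost without sgGal4 2, sgGal4 3 or sgHS2 2 (adjusted p = 0.0628, 0.0803 and 0.0931). Of 38 ribosomal protein genes 0 rose and 20 fell, or 29 adjusted over the list alone (camera adjusted p = 4.67e-05; adjusted p = 0.67 with an estimated correlation), with 36 fallen without sgGal4 1 and sgHS2 2.

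The other lists were not called in sgHS2 against sgGal4. None of 11 genes of the α-globin cluster passed the edgeR test (5 at an unadjusted p under 0.05), and of 17 genes neighbouring the β-globin cluster 2 rose and 2 fell, with RRM1 at log2 −0.64 ± 0.10 and TRIM21 at 0.89 ± 0.16. Numbers that rose and fell were 7 and 1 of 31 regulators of globin transcription (TAL1 log2 0.79 ± 0.14), 3 and 0 of 17 megakaryocyte genes, 0 and 3 of 19 myeloid genes and 1 and 6 of 12 fibroblast and epithelial genes. They were 2 and 6 of 10 biotin enzyme genes, 6 and 4 of 26 adhesion genes (ITGA4 log2 −3.92 ± 0.33), 4 and 4 of 22 p53 genes, 1 and 1 of 15 heat shock genes and 7 and 4 of 30 immediate early genes (EGR1 log2 1.31 ± 0.15). They were 5 and 2 of 15 BCR-ABL and STAT5 targets, 1 and 3 of 14 histone genes and 5 and 9 of 23 unfolded protein response genes. Adjusted over the list alone, the counts were the same except for 0 and 2 myeloid, 1 and 7 fibroblast and epithelial, and 0 and 0 heat shock genes. Camera adjusted p values of these lists lay between 0.0933 and 0.976. Median, mean and test differed in sign for adhesion genes (median 0.18, mean −0.05), BCR-ABL targets (median −0.09, mean 0.05) and p53 genes (medians near 0). Over all genes 4332 of 14406 were called in sgHS2 against sgGal4, with 2083 higher and 2249 lower, and 1682 changed at least 2-fold. With only the 2 groups in the fit 2306 genes were called.

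The comparison of sgHBG with sgGal4 addresses which genes differ when dCas9 is directed to the fetal globin promoters. HBBP1 was 5.53-fold higher in sgHBG (6.91 ± 0.983 CPM, n = 3) than in sgGal4 (1.24 ± 0.0441 CPM, n = 3), a log2 difference of 2.47 ± 0.27 (adjusted p = 5.7e-05). HBD was 1.56-fold higher (6.49 ± 0.701 against 4.22 ± 1.29 CPM, log2 0.64 ± 0.22, adjusted p = 0.0477). HBE1 (273 ± 13.7 CPM, log2 −0.32 ± 0.28, adjusted p = 0.414), HBG1 (61.2 ± 1.89 CPM, log2 −0.28 ± 0.33, adjusted p = 0.562) and HBG2 (84.3 ± 5.19 CPM, log2 −0.16 ± 0.33, adjusted p = 0.743) were not called. HBB had 0 reads in both groups. In the β-globin cluster 2 of 5 genes rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.271). The median of the list was −0.16 and its mean 0.47. The call of HBD was lost without any library of either group except sgGal4 1 (log2 0.47 to 0.72, adjusted p = 0.0726 to 0.152), and without a low-count filter (0.0571), with only the 2 groups in the fit (0.104) or in the RPKM values (log2 0.29, adjusted p = 0.35). Without sgGal4 1 the differences were 0.19 for HBE1, 0.39 for HBG1 and 0.51 for HBG2 (adjusted p = 0.41, 0.127 and 0.0442), HBG2 was thus called, and the list was called as well (camera adjusted p = 0.0301).

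Megakaryocyte genes rose in sgHBG. Of 17 genes 11 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 7.41e-09; adjusted p = 0.00817 with an estimated correlation). ITGA2B, the platelet integrin αIIb, was 4.33-fold higher (231 ± 1.61 against 53.3 ± 8.74 CPM, log2 2.12 ± 0.16, adjusted p = 3.74e-06). THBS1, thrombospondin, was 3.96-fold higher, ITGB3, the partner of ITGA2B, 3.48-fold higher, and SELP, P-selectin, had a log2 difference of 4.06 ± 0.58 (5.41 without sgGal4 3). In the erythroid membrane list 11 of 29 genes rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.00597; adjusted p = 0.477 with an estimated correlation; 0.0802 without sgGal4 1, sgHS2 2, sgHS1-5 2 and sgHS1-5 3). TRIM10, an erythroid ubiquitin ligase, had 176 reads against 3, a ratio of 50.8 (95% counting interval 17.1 to 249). In the interferon response list 15 of 29 genes rose and 3 fell, also adjusted over the list alone (camera adjusted p = 1.61e-08; adjusted p = 0.0241 with an estimated correlation), with SAMD9, an antiviral factor, 19.4-fold higher. In the cholesterol synthesis list 0 of 22 genes rose and 18 fell, or 19 adjusted over the list alone (camera adjusted p = 1.9e-19; adjusted p = 6.65e-05 with an estimated correlation), and CYP51A1 was 3.08-fold lower (log2 −1.63 ± 0.09, adjusted p = 2.47e-07).

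Of 38 ribosomal protein genes 0 rose and 28 fell in sgHBG, or 36 adjusted over the list alone (camera adjusted p = 6.01e-08; adjusted p = 0.634 with an estimated correlation). In the lymphoid list 6 of 16 genes rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.00955; adjusted p = 0.634 with an estimated correlation), and CD52 was 2.59-fold higher (48.0 ± 2.37 against 18.6 ± 4.6 CPM). In the MHC and antigen processing list 6 of 18 genes rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0294, 0.0528 without sgGal4 2 and 0.053 without sgGal4 3; adjusted p = 0.634 with an estimated correlation). In the proliferation list 1 of 30 genes rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.0453; adjusted p = 0.477 with an estimated correlation). The proliferation call was lost without sgGal4 2 (0.0528), sgGal4 3 (0.053), sgHBG 2 (0.0643), or sgHS1-5 2 and 3 (0.104), with a filter of 1 CPM in 3 libraries (0.0519) and with only the 2 groups in the fit (0.0729). The unfolded protein response list was not called (2 of 23 genes rose, 9 fell, camera adjusted p = 0.0618) but was called without sgGal4 1 (0.0301), sgGal4 3 (0.0299) or a low-count filter (0.049).

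The remaining lists were not called in sgHBG, with camera adjusted p values of 0.0618 to 0.999, and limma voom called the fibroblast and epithelial list (0.0453). None of 15 heat shock genes passed the edgeR test (5 at an unadjusted p under 0.05). Numbers that rose and fell were 0 and 2 of 11 α-globin cluster genes, 2 and 1 of 17 genes neighbouring the β-globin cluster, 1 and 3 of 31 globin regulators (TAL1 log2 0.88 ± 0.14), 1 and 1 of 20 heme biosynthesis genes and 2 and 0 of 19 myeloid genes (FCER1G log2 2.34 ± 0.46). They were 1 and 5 of 12 fibroblast and epithelial genes, 1 and 3 of 10 biotin enzyme genes, 5 and 3 of 26 adhesion genes (ITGB2 log2 3.499 ± 0.71), 3 and 1 of 22 p53 genes and 7 and 3 of 29 glycolysis and hypoxia genes (VEGFA log2 0.85 ± 0.10). They were 7 and 2 of 30 immediate early genes, 3 and 1 of 15 BCR-ABL and STAT5 targets and 3 and 1 of 14 histone genes. Adjusted over the list alone, the counts differed for α-globin cluster (0 and 1), globin regulator (1 and 1), biotin enzyme (2 and 3), adhesion (8 and 4), p53 (2 and 1), glycolysis and hypoxia (9 and 3), BCR-ABL target (3 and 2) and histone genes (5 and 1). Median, mean and test differed in sign for biotin enzymes, heme biosynthesis and myeloid genes, with medians of 0.00, 0.03 and −0.13 and means of −0.01, −0.02 and −0.09.

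Individual genes farthest from sgGal4 in sgHBG included several also named for sgHS2. Among the genes below, NAA11 and MAGEA8 were also lower in sgGal4 than in WT. NAA11, a testis-enriched acetyltransferase, was at least 25.1-fold higher (2.66 ± 0.138 CPM against 0 counts, adjusted p = 5.88e-06), MAGEA8 at least 26-fold higher (adjusted p = 3.09e-05) and the keratin KRT86 at least 26.3-fold higher (adjusted p = 0.000409). SASH3, a lymphocyte adaptor, had a log2 difference of 5.95 ± 0.999 (11.9 ± 0.945 against 0.205 ± 0.191 CPM, adjusted p = 0.00117; 6.80 without sgGal4 1). XIST was 101.5-fold higher (log2 6.67 ± 0.33, adjusted p = 1.65e-07), and TSIX had a log2 difference of 5.77 in the counts but 0.04 in the RPKM values without a filter. PDGFC, a growth factor, was at least 42.7-fold lower (adjusted p = 0.000174). CKAP4, a protein of the endoplasmic reticulum, was 30.9-fold lower (0.891 ± 0.155 against 27.9 ± 7.91 CPM, log2 −4.95 ± 0.43, adjusted p = 9.36e-06), and COL11A1 was 35.1-fold lower (log2 −5.13 ± 0.33, adjusted p = 1.86e-06). In sgHBG against sgGal4 3556 genes were called, 1738 higher and 1818 lower, and 1321 changed at least 2-fold. The number was 2211, 2072 and 2064 without sgHBG 1, 2 and 3, each with more higher than lower, and 2099 with only the 2 groups in the fit.

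The comparison of sgHS1-5 with sgGal4 addresses which genes differ when dCas9 is directed to several elements of the locus control region. HBG2 was 2.41-fold higher in sgHS1-5 (228 ± 52.9 CPM, n = 3) than in sgGal4 (94.9 ± 61.7 CPM, n = 3), a log2 difference of 1.27 ± 0.33 (adjusted p = 0.00929, or 0.0782 with only the 2 groups in the fit; log2 1.94 without sgGal4 1). HBBP1 was 2.83-fold higher (log2 1.502 ± 0.28, adjusted p = 0.00146). HBG1 had a log2 difference of 0.85 ± 0.33 that was not called (134 ± 27.9 CPM, adjusted p = 0.0546), but it was called without sgGal4 1 (log2 1.51, adjusted p = 3.04e-05) or sgHS1-5 2 (log2 1.02, adjusted p = 0.0466), without a low-count filter (0.0426), with DESeq2 (0.0321), with limma voom (0.0223) and in the RPKM values (0.0223). HBE1 (251 ± 55.5 CPM, log2 −0.44 ± 0.28, adjusted p = 0.221) and HBD (2.999 ± 0.504 CPM, log2 −0.48 ± 0.24, adjusted p = 0.127) were not called, and HBB had 0 reads. The direction of HBE1 turned without sgGal4 1 (log2 0.07). In the β-globin cluster 2 of 5 genes rose and 0 fell, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.325, and 0.0152 without sgGal4 1). HBZ, the embryonic α-like globin gene on chromosome 16, was 19.7-fold higher (129.8 ± 26.5 against 6.63 ± 1.17 CPM, log2 4.30 ± 0.23, adjusted p = 1.01e-07). HBA1, an adult α-globin gene, had a log2 difference of 1.86 ± 0.48 (adjusted p = 0.009, or 0.0712 with only the 2 groups in the fit; log2 2.53 without sgGal4 1). In the α-globin cluster 4 of 11 genes rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.065), and the list was called without sgGal4 1 (0.00247), sgHS1-5 2 (0.0114) or both sgHS1-5 2 and 3 (0.00364) and with only the 2 groups in the fit (0.0305). Of 17 genes neighbouring the β-globin cluster 2 rose and 5 fell (camera adjusted p = 0.552), and the olfactory receptor gene OR51B6 had 26 reads against 1, a ratio of 35.2 (95% counting interval 5.78 to 1440, adjusted p = 0.00177; log2 4.70, or 6.57 without sgGal4 3).

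The unfolded protein response and cholesterol synthesis lists fell in sgHS1-5, and the glycolysis and hypoxia list rose. In the unfolded protein response list 0 of 23 genes rose and 22 fell, also adjusted over the list alone (camera adjusted p = 1.09e-22; adjusted p = 0.00166 with an estimated correlation). ASNS, asparagine synthetase, was 12.2-fold lower (76.6 ± 10.8 against 933 ± 230 CPM, log2 −3.61 ± 0.17, adjusted p = 4.4e-08), and CHAC1, a glutathione-degrading enzyme, was 10.5-fold lower. INHBE, an activin subunit, was 28.6-fold lower (4.93 ± 1.02 against 141 ± 13.2 CPM, log2 −4.84 ± 0.14, adjusted p = 1e-09). In the cholesterol synthesis list 0 of 22 genes rose and 20 fell, or 21 adjusted over the list alone (camera adjusted p = 4.47e-23; adjusted p = 3.21e-05 with an estimated correlation). In the glycolysis and hypoxia list 23 of 29 genes rose and 1 fell, or 24 and 1 adjusted over the list alone (camera adjusted p = 2.67e-14; adjusted p = 0.00224 with an estimated correlation), and LDHA was 3.99-fold higher (1498 ± 116 against 376 ± 12.5 CPM, log2 2.00 ± 0.09, adjusted p = 4.34e-08). Of 38 ribosomal protein genes 0 rose and 35 fell, or 36 adjusted over the list alone (camera adjusted p = 1.79e-07; adjusted p = 0.548 with an estimated correlation). With only sgHS1-5 1 left in its group, 20 unfolded protein response, 17 cholesterol synthesis and 3 ribosomal protein genes fell and 19 glycolysis and hypoxia genes rose, and all 4 lists were called with the preset correlation.

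**Figure D3:**
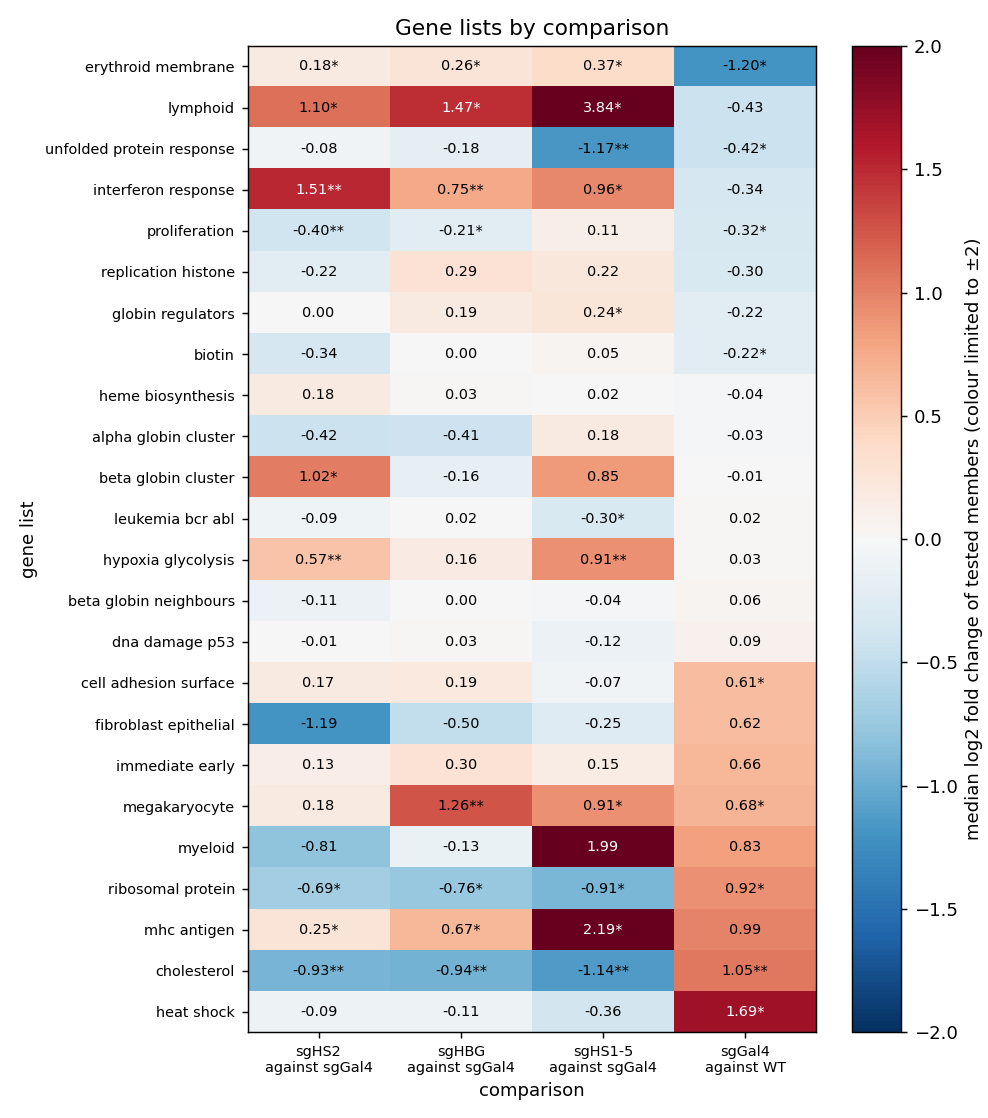
Median log2 difference (colour, limited to ±2) of the 24 gene lists in sgHS2, sgHBG and sgHS1-5 against sgGal4 and in sgGal4 against WT. A single asterisk marks a camera adjusted p under 0.05 and a double asterisk marks lists that also passed with an estimated correlation, which were 4, 3, 3 and 1 lists in this order.

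The lymphoid, MHC, erythroid membrane, interferon and megakaryocyte lists rose in sgHS1-5 with the preset correlation, but none was called with an estimated correlation. Replicates 2 and 3 of sgHS1-5 also held 2090 and 508 CPM of transcripts near 0 in the other groups. Replicate 1 held 77.2 CPM of them, against 3.32 to 6.28 CPM in the other groups, a gap that the choice of transcripts favours. Results with sgHS1-5 1 alone may thus not be free of such transcripts. In the lymphoid list 16 of 16 genes rose, also adjusted over the list alone (camera adjusted p = 1e-08; adjusted p = 0.257 with an estimated correlation), but 7 of 13 rose with sgHS1-5 1 alone. CD3D was 12.6-fold higher (25.1 ± 2.69 against 2.12 ± 1.52 CPM, log2 3.65 ± 0.37, adjusted p = 1.72e-05). In the MHC and antigen processing list 14 of 18 genes rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.00126; adjusted p = 0.38 with an estimated correlation), against 5 and 2 of 16 with sgHS1-5 1 alone. In the erythroid membrane list 11 of 29 genes rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.00833; adjusted p = 0.33 with an estimated correlation), and RHD, a blood group antigen, was 5.63-fold higher (log2 2.49 ± 0.18, adjusted p = 1.22e-06). In the interferon response list 16 of 29 genes rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.00833; adjusted p = 0.284 with an estimated correlation), with SAMD9 23.9-fold higher. In the megakaryocyte list 7 of 17 genes rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.014; adjusted p = 0.257 with an estimated correlation), but the call was lost without sgGal4 1 (0.0562) or without sgHS1-5 2 and 3 (0.0567). Of 31 globin regulators 11 rose and 0 fell, or 9 and 0 adjusted over the list alone (camera adjusted p = 0.0285, 0.0683 without sgHS1-5 1; adjusted p = 0.118 with an estimated correlation), and ZFPM1, a partner of GATA1, was 2.28-fold higher. Of 15 BCR-ABL and STAT5 targets 0 rose and 6 fell, or 1 and 6 adjusted over the list alone (camera adjusted p = 0.014, 0.0697 without sgHS1-5 2 and 3; adjusted p = 0.284 with an estimated correlation), and SOCS2, an inhibitor of cytokine signalling, was 2.16-fold lower. Without sgGal4 1, sgHS2 2, sgHS1-5 2 and sgHS1-5 3, the calls of the interferon (0.149) and MHC lists (0.0792) were lost.

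The named genes farthest above sgGal4 in sgHS1-5 differed in level between its libraries. MPO, a granulocyte enzyme, had 19.4, 1415 and 264 CPM in sgHS1-5 1, 2 and 3 against 0.219 ± 0.106 CPM in sgGal4 (2514-fold higher, adjusted p = 0.000172; 636-fold without sgHS1-5 2). The chemokine receptor CXCR4 averaged 34.9 ± 42.8 CPM and was at least 346-fold higher (adjusted p = 0.00262; log2 11.40, or 9.75 without sgHS1-5 2). With limma voom neither MPO (adjusted p = 0.08) nor CXCR4 (0.0542) was called. The B cell gene MS4A1 was at least 167-fold higher (adjusted p = 0.011; log2 10.36, or 8.92 without sgHS1-5 2) and was not called with DESeq2 (adjusted p = 0.0722). FLI1, a megakaryocyte transcription factor, had a log2 difference of 5.33 ± 1.17 (adjusted p = 0.00416; 3.47 without sgHS1-5 2) but of −0.25 without sgHS1-5 2 and 3, and was not called with limma voom (adjusted p = 0.144). At the other end, CPZ, a carboxypeptidase, was 28.9-fold lower (2.11 ± 0.419 against 61.4 ± 1.64 CPM, log2 −4.86 ± 0.17, adjusted p = 3.4e-09), and TWIST1, a transcription factor of mesenchymal cells, was 26.6-fold lower (log2 −4.74 ± 0.29, adjusted p = 3.48e-07). CLCA1 was at least 34-fold lower (adjusted p = 0.000151).

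The remaining lists were not called in sgHS1-5, with camera adjusted p values of 0.065 to 0.882. In the proliferation list 9 of 30 genes rose and 1 fell (camera adjusted p = 0.065, and 0.0184 without sgGal4 1 and 0.0296 without sgHS1-5 3), with the proliferation marker MKI67 3.44-fold higher. Of 15 heat shock genes 0 rose and 6 fell (camera adjusted p = 0.065; 0.0358 without sgGal4 2, 0.0271 without sgGal4 3, 0.0421 without sgHS1-5 1, 0.00771 without a low-count filter and 0.0288 with limma voom). In the myeloid list 11 of 19 genes rose and 2 fell (camera adjusted p = 0.0895, with 2.27e-05 without sgHS1-5 1, 0.0379 without a low-count filter and 0.0227 with the replicate block), but with sgHS1-5 1 alone 2 of 15 rose and 5 fell, and in the heme biosynthesis list 6 of 20 rose and 2 fell (camera adjusted p = 0.181, and 0.0363 without sgGal4 1). Numbers that rose and fell were 4 and 3 of 10 biotin enzyme genes, 7 and 7 of 26 adhesion genes, 3 and 7 of 22 p53 genes (BBC3 log2 −1.83 ± 0.20), 3 and 4 of 12 fibroblast and epithelial genes, 10 and 7 of 30 immediate early genes (MYC log2 1.13 ± 0.18) and 4 and 1 of 14 histone genes. Adjusted over the list alone, the counts of these lists differed for biotin enzyme (5 and 4), immediate early (10 and 8), myeloid (12 and 2) and histone genes (5 and 1). Medians and means differed in sign for adhesion genes (−0.07 and 0.75), fibroblast and epithelial genes (−0.25 and 0.15) and genes neighbouring the β-globin cluster (−0.04 and 0.23). In sgHS1-5 against sgGal4 5823 genes were called, 2920 higher and 2903 lower, and 2433 changed at least 2-fold. With sgHS1-5 1 alone in its group 2475 genes were called, and with only the 2 groups in the fit 2203.

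The comparison of sgGal4 with WT addresses how cells with dCas9, BirA and a non-targeting sgRNA differ from unmodified K562 cells. HBD was 3.84-fold higher in sgGal4 (4.22 ± 1.29 CPM, n = 3) than in WT (1.07 ± 0.157 CPM, n = 2), a log2 difference of 1.94 ± 0.29 (adjusted p = 0.000197). HBZ was 2.01-fold lower (log2 −1.01 ± 0.24, adjusted p = 0.00508, or 0.0541 in the RPKM values without a filter). HBE1 (341 ± 176 against 344 ± 3.07 CPM, log2 −0.01 ± 0.31, adjusted p = 0.984), HBG1 (log2 0.30 ± 0.37, adjusted p = 0.549), HBG2 (log2 −0.41 ± 0.36, adjusted p = 0.389) and HBBP1 (log2 −0.62 ± 0.32, adjusted p = 0.136) were not called. Without sgGal4 1, HBE1 and HBG2 were called at log2 differences of −0.52 (adjusted p = 0.0231) and −1.08 (adjusted p = 0.000341), and that of HBG1 was −0.36 and not called. HBB had 14 reads in WT, 12 of them in a single library, and 0 in sgGal4, so it was at least 6.18-fold higher in WT. The low-count filter left HBB out of the test, and it was called lower in sgGal4 without that filter (log2 −5.69, adjusted p = 0.0263), without sgHS1-5 2 and 3 (log2 −5.74, adjusted p = 0.0287), without these, sgGal4 1 and sgHS2 2 (log2 −5.79, adjusted p = 0.000811) and in the RPKM values without a filter (log2 −1.08, adjusted p = 0.000117). In the β-globin cluster 1 of 5 genes rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.835). Median and mean of this list differed in sign (−0.01 and 0.24).

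Erythroid membrane genes fell and heat shock genes rose in sgGal4 against WT with the preset correlation. In the erythroid membrane list 1 of 29 genes rose and 20 fell, or 1 and 23 adjusted over the list alone (camera adjusted p = 5.54e-11; adjusted p = 0.068 with an estimated correlation). In the heat shock list 13 of 15 genes rose and 0 fell, also adjusted over the list alone (camera adjusted p = 5.65e-12; adjusted p = 0.0787 with an estimated correlation). HSPA8, a constitutive chaperone, was 4.52-fold higher (2134 ± 184 against 472 ± 15.7 CPM, log2 2.18 ± 0.12, adjusted p = 3.82e-08). In the cholesterol synthesis list 17 of 22 genes rose and 0 fell, or 18 adjusted over the list alone (camera adjusted p = 1.53e-09; adjusted p = 0.0015 with an estimated correlation), and SQLE, squalene epoxidase, was 6.69-fold higher (log2 2.74 ± 0.15, adjusted p = 3.88e-08). In the adhesion list 12 of 26 genes rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.000395; adjusted p = 0.0708 with an estimated correlation), and CD44, the hyaluronan receptor, was 53.5-fold higher (236 ± 4.4 against 4.41 ± 0.7 CPM, log2 5.74 ± 0.18, adjusted p = 1.32e-09). Of 38 ribosomal protein genes 31 rose and 0 fell, or 35 adjusted over the list alone (camera adjusted p = 0.000346; adjusted p = 0.79 with an estimated correlation). In the proliferation list 3 of 30 genes rose and 15 fell, or 3 and 16 adjusted over the list alone (camera adjusted p = 0.00324; adjusted p = 0.18 with an estimated correlation).

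Biotin enzymes, whose cofactor BirA attaches, were among the called lists in sgGal4 against WT: 4 of 10 genes rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.0353; adjusted p = 0.131 with an estimated correlation). PC, pyruvate carboxylase, was 5.33-fold lower (6.33 ± 0.319 against 33.8 ± 0.549 CPM, log2 −2.41 ± 0.14, adjusted p = 6.05e-08), and HLCS, the human biotin ligase, was 1.87-fold lower. The biotin call was lost without sgGal4 1 (adjusted p = 0.101), sgGal4 3 (0.0624), both sgGal4 1 and sgHS2 2 (0.26) or these and sgHS1-5 2 and 3 (0.356). It was also lost without a low-count filter (0.114), with the replicate block (0.168), with limma voom (0.28) and with only the 2 groups in the fit (0.224). In the unfolded protein response list 3 of 23 genes rose and 7 fell, or 3 and 8 adjusted over the list alone (camera adjusted p = 0.0353, 0.081 without sgGal4 3; adjusted p = 0.393 with an estimated correlation). The replicate block (0.107), limma voom (0.0817) and a fit with only the 2 groups (0.0556) did not call it. In the megakaryocyte list 6 of 17 genes rose and 1 fell, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.0425; adjusted p = 0.342 with an estimated correlation). That call was lost without WT 1 (0.104), WT 2 (0.0815), sgGal4 2 (0.0716), sgGal4 3 (0.081) or a low-count filter (0.0763), and with the replicate block (0.114) or limma voom (0.13). Among lists that were not called, numbers that rose and fell were 0 and 2 of 11 α-globin cluster genes, 3 and 3 of 17 genes neighbouring the β-globin cluster, 3 and 10 of 31 globin regulators (TAL1 log2 −1.56 ± 0.16) and 5 and 8 of 20 heme biosynthesis genes (FECH log2 −1.66 ± 0.11). They were 6 and 1 of 19 myeloid genes, 1 and 2 of 16 lymphoid genes, 5 and 2 of 12 fibroblast and epithelial genes, 6 and 7 of 29 glycolysis and hypoxia genes and 7 and 7 of 29 interferon response genes. They were 5 and 3 of 18 MHC genes, 7 and 5 of 22 p53 genes, 12 and 3 of 30 immediate early genes, 2 and 3 of 15 BCR-ABL and STAT5 targets and 1 and 6 of 14 histone genes. Adjusted over the list alone, the counts of these lists differed for lymphoid (1 and 1) and MHC genes (6 and 3). Camera adjusted p values lay between 0.121 and 0.893, the myeloid list was called without sgHS1-5 2 and 3 (0.0483), and the immediate early list with only the 2 groups in the fit (0.0472). Test and mean differed in sign for glycolysis and hypoxia genes and genes neighbouring the β-globin cluster (means 0.15 and 0.24, test downward), and median and mean for BCR-ABL targets (0.02 and −0.12).

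Single genes distinguished sgGal4 from WT by wide margins. SLC6A15 was at least 366-fold higher in sgGal4 (50.1 ± 9.32 CPM against 0 counts, adjusted p = 1.17e-08) and LMCD1, a LIM domain protein, at least 218-fold higher (adjusted p = 5.48e-08). NAA11 was at least 215-fold lower (adjusted p = 2.49e-08), the cancer-testis antigen CTAG2 at least 90.4-fold lower (adjusted p = 7.22e-06) and MAGEA8 at least 66.6-fold lower (adjusted p = 1.48e-06). FN1 was 222-fold lower (1.32 ± 0.417 against 306 ± 1.3 CPM, log2 −7.79 ± 0.73, adjusted p = 3.85e-06). In this comparison 6103 genes were called, 3276 higher and 2827 lower, and 2927 changed at least 2-fold. The number was 3906 without WT 1, 3943 without WT 2 and 3502 with only the 2 groups in the fit.

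Genes of chromosomes 4, 15 and X were lower in sgGal4 than in WT. Their median log2 differences were −0.40, −0.49 and −0.66, against 0.09 over the genes of the other chromosomes, whose medians lay between −0.09 and 0.27. Parts of other chromosomes departed as well, which whole-chromosome medians hide. In windows of 20 neighbouring genes, most of windows 37 to 72 of chromosome 1 lay above 0.09, up to 0.95 (window 59). Windows 1 to 36 lay on both sides. On chromosome 12, windows 1 to 7 lay between 0.44 (window 7) and 0.80 (window 5). On chromosome X, 245 of 493 genes fell and 44 rose. Of 456 genes on chromosome 15, 196 fell and 33 rose, and of 518 genes on chromosome 4, 201 fell and 70 rose. In the targeting groups against sgGal4 the medians of chromosomes 4, 15 and X were 0.24, 0.42 and 0.59 in sgHS2, 0.06, 0.41 and 0.35 in sgHBG and 0.27, 0.35 and 0.32 in sgHS1-5. The other chromosomes lay between −0.15 and 0.08, −0.25 and 0.06, and −0.11 and 0.21, so chromosome 4 in sgHBG was close to the highest of these. Against WT the medians of chromosomes 4, 15 and X were −0.17, −0.04 and −0.03 in sgHS2, −0.32, −0.10 and −0.23 in sgHBG and −0.15, −0.16 and −0.33 in sgHS1-5. The genes of the other chromosomes then had medians of 0.04, 0.04 and 0.08, and these chromosomes lay between −0.11 and 0.17, −0.20 and 0.21, and −0.05 and 0.21. Chromosomes 15 and X in sgHS2 and chromosome 15 in sgHBG were within these ranges. In sgHBG chromosome 7 alone set the low end (−0.197). The next lowest of the other chromosomes was chromosome 22 (−0.089), above chromosome 15.

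**Figure D4:**
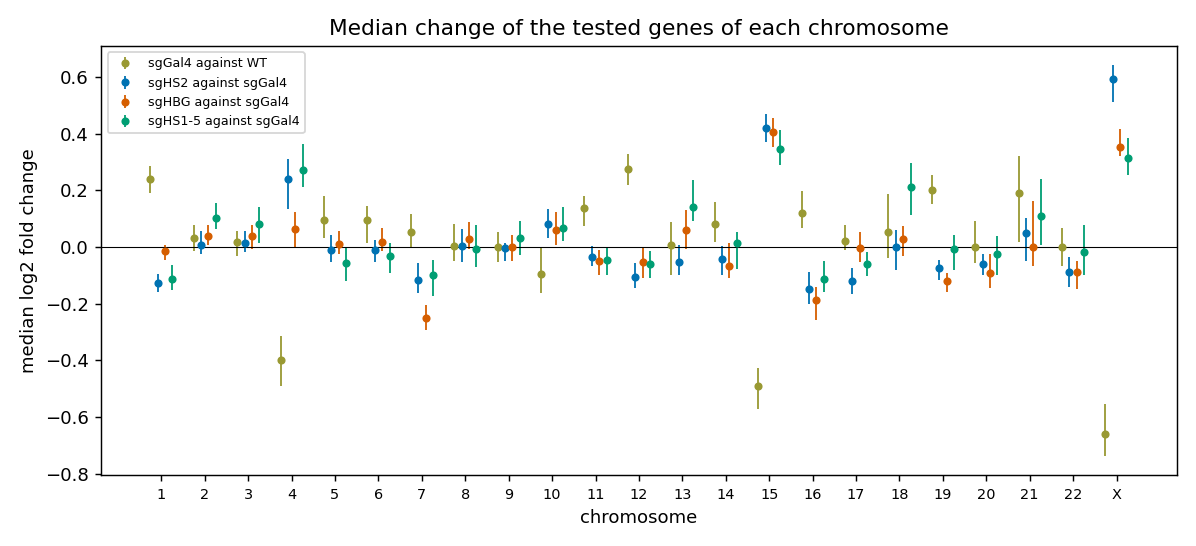
Median log2 difference of the tested genes of each chromosome (1 to 22 and X) with its 95% interval, for sgHS2, sgHBG and sgHS1-5 against sgGal4 and sgGal4 against WT. The interval comes from resampling the genes of a chromosome. It treats genes as independent and holds no variation between libraries or cell populations. In sgGal4 against WT the medians of chromosomes 4, 15 and X are −0.40, −0.49 and −0.66 and those of the others lie between −0.09 and 0.27.

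The overlap of the 3 comparisons with sgGal4 addresses how far the targeting sgRNAs share their differences. In all 3 comparisons 686 genes were higher and 819 lower, where independent lists would share 50.9 and 57.2. A further 389 genes were called higher in some comparison and lower in another, whether or not they were called in all 3. The 3 sgGal4 libraries serve all 3 comparisons and cannot be divided into separate controls of at least 2, so a part of the overlap may stem from these shared libraries. Of the 686 genes that were higher in all 3, 434 (63.3%) were lower in sgGal4 than in WT and 40 higher. Of the 819 genes that were lower in all 3, 596 (72.8%) were higher in sgGal4 than in WT and 13 lower. Over all 14406 genes 2827 were lower and 3276 higher in sgGal4 than in WT. The sgGal4 libraries enter both sides of this agreement and favour it, and the value expected from them alone was not computed. Of the 671 genes higher in all 3 with a known chromosome, 197 (29.4%) lay on chromosomes 4, 15 and X. Of the 811 genes lower in all 3, 37 (4.56%) lay there. These chromosomes held 1467 of all 14145 genes (10.4%). They were singled out for low levels in sgGal4 against WT, and both gene sets are defined against the same sgGal4 libraries. The choice thus favours these shares, and the value expected from it alone was not computed. Pairs shared 1192 higher and 1198 lower genes for sgHS2 and sgHBG, 914 and 1080 for sgHS2 and sgHS1-5, and 974 and 1220 for sgHBG and sgHS1-5.

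Comparisons between targeting sgRNAs address whether their groups differ, and the sgGal4 libraries entered only through the filter, scaling and dispersion of the joint fit. Effects of the sgRNAs cannot be told apart here from other differences between the cell populations. Between sgHS2 and sgHBG, HBE1 was 2.53-fold and HBG2 3.22-fold higher in sgHS2, while HBBP1 was lower. LIN28A, an RNA-binding pluripotency factor, was 58.4-fold lower in sgHS2 (0.12 ± 0.104 against 8.09 ± 0.27 CPM, log2 −5.87 ± 0.45, adjusted p = 1.66e-05), and PNCK, a calmodulin-dependent kinase, was 6.12-fold higher (21.4 ± 5.41 against 3.51 ± 1.09 CPM, log2 2.61 ± 0.29, adjusted p = 0.000185). Of 29 glycolysis and hypoxia genes 14 rose and 0 fell in sgHS2 against sgHBG, or 23 adjusted over the list alone (camera adjusted p = 9.67e-21; adjusted p = 0.00144 with an estimated correlation). Of 17 megakaryocyte genes 0 rose and 8 fell, or 9 adjusted over the list alone (camera adjusted p = 2.6e-10; adjusted p = 0.0114 with an estimated correlation). FLI1 had 3 reads in sgHS2 against 235, a ratio of 75.8 in favour of sgHBG (95% counting interval 25.6 to 370, adjusted p = 0.0237), and its call was lost without any single library of either group (adjusted p = 0.0605 to 0.0938; log2 −6.06, or −6.97 without sgHS2 2). There were 1284 genes called, 542 higher and 742 lower, against 548 to 722 without any single library of either group, 3424 without sgGal4 1 and sgHS2 2 and 3510 with only the 2 groups in the fit.

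In sgHS1-5 against sgHBG, 0 of 23 unfolded protein response genes rose and 17 fell, also adjusted over the list alone (camera adjusted p = 8.63e-23; adjusted p = 0.00154 with an estimated correlation), and 22 of 29 glycolysis and hypoxia genes rose and 1 fell, or 22 and 3 adjusted over the list alone (camera adjusted p = 4.73e-17; adjusted p = 0.00154 with an estimated correlation). SELP had 1 read in sgHS1-5 against 176, a ratio of 113 (95% counting interval 19.9 to 4470, adjusted p = 0.000153; log2 −6.47, or −8.72 without sgHS1-5 3). There were 3628 genes called, 1790 higher and 1838 lower, with 1372 for sgHS1-5 1 alone in its group, 2394 without sgHBG 1, 2322 without sgHBG 2 and 5298 with only the 2 groups in the fit. In sgHS1-5 against sgHS2, 24 of 30 proliferation genes rose and 0 fell, or 27 adjusted over the list alone (camera adjusted p = 3.15e-11; adjusted p = 0.0111 with an estimated correlation). Of 23 unfolded protein response genes 0 rose and 18 fell, also adjusted over the list alone (camera adjusted p = 1.15e-17; adjusted p = 0.00806 with an estimated correlation). KLHDC7B, a kelch domain protein, was 38.7-fold lower (0.751 ± 0.31 against 30.1 ± 4.72 CPM, log2 −5.27 ± 0.26, adjusted p = 9.2e-08). There were 5608 genes called, 2936 higher and 2672 lower, and 2675 with sgHS1-5 1 alone. MPO had the highest log2 difference of the named genes in both comparisons, with values of 12.40 and 11.99 that became 10.42 and 10.01 without sgHS1-5 2, and the first became 13.21 without sgHBG 2. With limma voom it was called in neither (adjusted p = 0.136 and 0.0895).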

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

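The joint test of GC content and transcript length on the chromosomes and the test of GC content on sgGal4 1 and sgHS2 2 were chosen before their results were seen. The other tests of explanations, that of transcript length on sgGal4 1 and sgHS2 2 included, were chosen after. The comparisons between targeting sgRNAs were planned.

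The β-globin genes differed between the targeting sgRNAs, with every library of the higher group above every library of the other (3 of 3 libraries against 3). HBE1, HBG1 and HBG2 were higher in sgHS2 than in sgHBG, with log2 differences of 1.34, 1.21 and 1.69 (adjusted p = 0.0107, 0.038 and 0.00792), while HBBP1 was lower (log2 −1.05, adjusted p = 0.0172). HBG1 and HBG2 were also higher in sgHS1-5 than in sgHBG (log2 1.13 and 1.43, adjusted p = 0.0247 and 0.00771), while HBD and HBBP1 were lower (log2 −1.12 and −0.964, adjusted p = 0.00398 and 0.0127). Against sgHS2, sgHS1-5 had lower HBE1 (log2 −1.46, adjusted p = 0.00146) and HBD (log2 −1.01, adjusted p = 0.00433).

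The RPKM table held 539 genes absent from the count table, of which 192 passed the filter. With limma-trend 61 of them were called in sgHS2 against sgGal4, 61 in sgHBG against sgGal4, 78 in sgHS1-5 against sgGal4 and 92 in sgGal4 against WT. For the adhesion receptor gene GPR126, log2 of RPKM plus 1 differed by −1.71 in sgHS2 against sgGal4 and by 2.07 in sgGal4 against WT. Its mean RPKM was 0.288 in sgHS2, 3.48 in sgGal4 and 0.00387 in WT, so these differences are not fold changes.

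The high levels in sgHS1-5 2 and 3 of 138 transcripts near 0 elsewhere, CXCR4 among them, were the first pattern. A candidate explanation is RNA of other human cells: CDKN2A, CDKN2B and MTAP, which the K562 genome lacks, had 260 reads in the sgHS1-5 libraries (41, 31 and 129 in sgHS1-5 2) against 7 in the other 11 libraries. The most abundant myeloid genes, MPO and LYZ, had 1415 and 521 CPM in sgHS1-5 2, but 13 of 19 tested myeloid list genes also averaged at least 1 CPM in the other 11 libraries, and 2 of the 138 transcripts were on the myeloid list. The median ratio of CPM between sgHS1-5 2 and 1 was 18.8 in the 138 transcripts, which were chosen for a high level in any sgHS1-5 library. A difference in depth, at a ratio of 1.19, was argued against by 29 transcripts chosen by sgHS1-5 3 alone, whose median ratio between sgHS1-5 2 and 1 was 28.5 (quartiles 21.7 and 43.3). A response of K562 cells was argued against for these 3 genes by the same 260 reads, since an absent gene cannot respond. For the other transcripts such a response cannot be told apart from RNA of other cells. The summed level was 27.1 times higher in sgHS1-5 2 than in sgHS1-5 1, which carry the same sgRNAs, but the replicate lines may have drifted. RNA of other cells would also lower the share of the cells' own erythroid and heme genes. Of 40 such genes, 31 were lower in sgHS1-5 2 than in sgHS1-5 1 (median log2 −0.426). In sgHS1-5 3, 29 were lower (median log2 −0.061). A drifted line could show lower levels as well.

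Low levels of genes on chromosomes 4, 15 and X in sgGal4 against WT were the second pattern. It was not due to sgGal4 1 alone, since without it the highest of the 3 medians still lay at −0.472 from that of the other chromosomes (log2). With trends on GC content and transcript length removed the gap was −0.466. Of 71 windows of 20 neighbouring genes on these chromosomes 68 (95.8%) lay below the median of the others, but the chromosomes were chosen for low medians of the same values, so the windows do not support a cause. Against the same 2 WT libraries, the medians of chromosomes 4, 15 and X were −0.17, −0.04 and −0.03 in sgHS2, −0.32, −0.10 and −0.23 in sgHBG and −0.15, −0.16 and −0.33 in sgHS1-5, each nearer 0 than in sgGal4. Chromosomes 15 and X in sgHS2 and chromosome 15 in sgHBG lay within the range of the other chromosomes (−0.11 to 0.17 and −0.20 to 0.21). Chromosome 15 in sgHBG did so only because of chromosome 7 (−0.197). How far the shared WT libraries account for these values was not tested. Fewer copies of these chromosomes cannot be told apart from other reasons for lower levels, since no DNA data were used here.

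The shared deviation of sgGal4 1 and sgHS2 2 from their groups was the third pattern, with a correlation across genes of 0.622 (genes are not independent replicates). Long transcripts were low and short transcripts high in both libraries, which may point to RNA quality, a property the labels do not give. The correlation was 0.518 after the trend on transcript length was removed and 0.577 after that on GC content. Both were taken from the longest annotated transcript of a gene, which may not be the one expressed. The remaining correlation thus cannot exclude length or GC content as the whole cause. RNA of other cells, the candidate explanation for sgHS1-5, was argued against by 140 transcripts near 0 in the other 9 libraries, chosen without these 2. These transcripts summed to 7.23 and 5.04 CPM in sgGal4 1 and sgHS2 2 and 2070 CPM in sgHS1-5 2. The summed level was at most 1.37 times that of the highest other replicate of the same group. No biological explanation was tested.

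The numbers of called genes were set against all 10 divisions of the 6 libraries into 3 and 3 for each pair of groups, which are too few for a share under 0.05. The real division alone, 1 of 10 in each case, reached its count. It gave 4332 genes for sgHS2, 3556 for sgHBG and 5823 for sgHS1-5 against sgGal4, 1284 for sgHS2 against sgHBG, 3628 for sgHS1-5 against sgHBG and 5608 for sgHS1-5 against sgHS2. The highest other division gave 0 genes with edgeR in each case, with 2905, 1093, 2660, 122, 892 and 1144 genes at an unadjusted p under 0.05. Each other division mixes libraries of both groups, so the difference between the groups adds to the spread within each side. This lowers the counts of these divisions, so their 0 is not a value for unchanged groups and no conclusion is drawn from it.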

How the results depend on the processing

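The fits without sgGal4 1 and sgHS2 2, without sgHS1-5 2 and 3, and without these 4 libraries were chosen after the data were seen. Of 98 top-ranked named gene results checked 1881 times under the alternatives, 1840 checks kept direction and call, 41 lost the call and 0 reversed. These genes were chosen in the same libraries for a call, no overlap between the groups and the largest differences. The choice favours such agreement, so no conclusion on stability is drawn from these counts. Of all 481 named results, 8989 of 9414 checks kept both, 316 lost the call, 84 gained it and 25 reversed. OR51B6, HMOX1 and IRAK3 did not pass the low-count filter with sgHS1-5 1 alone in its group and could not be tested there. Limma voom did not call MPO (adjusted p = 0.08) and CXCR4 (0.0542) in sgHS1-5 against sgGal4. Over the alternatives, the adjusted p in sgHS2 against sgGal4 ranged from 8.43e-40 to 0.0827 for HBE1, 5.75e-31 to 0.169 for HBG1 and 1.6e-42 to 0.0473 for HBG2. It ranged from 2.28e-39 to 0.0782 for HBG2 in sgHS1-5, and in sgHBG from 3.29e-13 to 0.000867 for HBBP1 and 5.75e-05 to 0.441 for HBD. Unless stated, the cause was not tested.

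Fits with only the compared groups called 2306 genes for sgHS2, 2099 for sgHBG and 2203 for sgHS1-5 against sgGal4 and 3502 for sgGal4 against WT. For sgHS2 against sgHBG the number rose from 1284 to 3510. These fits have fewer residual degrees of freedom, but the reason for the changes was not tested. The overlap of all 3 was then 550 genes, and 2, 1 and 1 β-globin genes were called in sgHS2, sgHBG and sgHS1-5. The requirement of a 2-fold change, which by construction lowers counts, left 1682, 1321, 2433 and 2927 genes in the 4 comparisons with sgGal4 or WT. It left 457 for sgHS2 against sgHBG, 1469 for sgHS1-5 against sgHBG and 2312 for sgHS1-5 against sgHS2. Without a low-count filter, 1 β-globin gene was called in sgHBG and 2 in sgGal4 against WT. With the replicate block, 1 β-globin gene was called in sgHBG, although the numbers did not pair libraries. An estimated correlation left 4, 3, 3 and 1 gene lists called, against 9, 8, 11 and 9 with the preset, and fry called 14 in sgHS2, 13 in sgHBG and 15 in sgGal4 against WT.

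Without sgGal4 1 and sgHS2 2, 5378 genes were called for sgHBG against sgGal4, 3424 for sgHS2 against sgHBG and 6900 for sgHS1-5 against sgHBG, the overlap was 2313, and 3 β-globin genes were called in sgGal4 against WT. Without sgHS1-5 2 and 3, 2475 genes were called for sgHS1-5 against sgGal4, 1372 against sgHBG and 2675 against sgHS2, the overlap was 954, and 2 β-globin genes were called in sgGal4 against WT. Without all 4 libraries, 8424 genes were called for sgHS2 and 7959 for sgHBG against sgGal4, 10069 for sgGal4 against WT, 6273 for sgHS2 against sgHBG and 6165 for sgHS1-5 against sgHBG. The overlap was then 2887, and 5, 4 and 5 β-globin genes were called in sgHBG, sgHS1-5 and sgGal4 against WT.

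Leaving out each library in turn gave 3029 to 5474 called genes and 2 to 5 β-globin genes for sgHS2 against sgGal4, 2064 to 4068 and 1 to 3 for sgHBG, 4424 to 6618 and 2 to 3 for sgHS1-5, and 3906 to 7348 and 1 to 3 for sgGal4 against WT. It gave 548 to 722 for sgHS2 against sgHBG, 2322 to 3422 for sgHS1-5 against sgHBG and 4293 to 5114 for sgHS1-5 against sgHS2, with an overlap of 1043 to 1738.

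Reversed directions concerned β-globin genes and, in fits without sgHS1-5 2 and 3, FLI1, whose log2 difference with all libraries was 5.33. In sgHBG against sgGal4, HBG2 (log2) was 0.0345 with limma voom, 0.000506 with 0.1 added to RPKM, 0.50 without sgGal4 1 and sgHS2 2 and 0.51 without 4 libraries. In the last 2 settings HBE1 was 0.18 and 0.19 and HBG1 0.38 and 0.39. With each library left out in turn HBG2 ranged from −0.422 to 0.508, HBE1 from −0.522 to 0.189 and HBG1 from −0.529 to 0.385, each highest without sgGal4 1. In sgHS1-5 against sgGal4, HBE1 was 0.0465 and 0.27 in these settings and −0.643 to 0.0673 with each library left out in turn, HBD was 0.0317 without 4 libraries, and FLI1 was −0.25 without sgHS1-5 2 and 3 and −0.38 without 4 libraries. In sgGal4 against WT, HBG1 was −0.0674 with 1 added to RPKM, −0.0686 with 0.1 added, −0.0674 without an RPKM filter, −0.36 without sgGal4 1 and sgHS2 2 and −0.36 without 4 libraries. With each library left out in turn HBG1 ranged from −0.364 to 0.551 and HBE1 from −0.521 to 0.19. The reversals of HBE1, HBG1 and HBG2 without sgGal4 1 go with the removal of that library, whose levels of these genes were the highest of its group. For HBD and FLI1 in sgHS1-5 the reason was not tested.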

Other observations

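The comparisons of targeting sgRNAs with WT were chosen after the data were seen. HBD was higher than in WT in each targeting group, 5.55-fold in sgHS2 (log2 2.47 ± 0.29, adjusted p = 3.64e-05), 5.98-fold in sgHBG (log2 2.58 ± 0.29, adjusted p = 2.51e-05) and 2.76-fold in sgHS1-5 (log2 1.46 ± 0.30, adjusted p = 0.00201), as it was in sgGal4. HBE1 was 2.01-fold higher than in WT in sgHS2 (log2 1.01 ± 0.32, adjusted p = 0.0262) and was not called in sgHBG (log2 −0.33, adjusted p = 0.445) or sgHS1-5 (log2 −0.45, adjusted p = 0.256). HBG1 was higher in sgHS2 (log2 1.23 ± 0.38, adjusted p = 0.0238) and sgHS1-5 (log2 1.15 ± 0.38, adjusted p = 0.0263), and its log2 difference was 0.02 in sgHBG (adjusted p = 0.976). HBG2 was higher in sgHS2 (log2 1.11 ± 0.38, adjusted p = 0.0373) and was not called in sgHS1-5 (log2 0.86, adjusted p = 0.0808) or sgHBG (log2 −0.57, adjusted p = 0.251).

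HBBP1 was higher than in WT in sgHBG (3.59-fold, log2 1.84 ± 0.29, adjusted p = 0.000359) and sgHS1-5 (1.84-fold, log2 0.88 ± 0.30, adjusted p = 0.0318), and not called in sgHS2 (log2 0.80 ± 0.30, adjusted p = 0.0542). HBZ was 9.83-fold higher than in WT in sgHS1-5 (129.8 ± 26.5 CPM, n = 3, against 13.2 ± 0.285 CPM, n = 2, adjusted p = 6.79e-07), and HBA1 was 3.56-fold higher (adjusted p = 0.016). HBB, with 14 reads in WT, was at least 7.13-fold lower in sgHBG and at least 4.56-fold lower in sgHS1-5. Over all genes, 4769 were called in sgHS2, 4844 in sgHBG and 6182 in sgHS1-5 against WT.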
